A study of Mus musculus with 8 samples.

How the data were processed

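RNA-seq libraries were made from total liver RNA extracted with TRIzol, prepared with TruSeq reagents and sequenced on an Illumina instrument, per the labels' protocols. The submitters' processing notes name Subread 1.5.2, featureCounts, DESeq2 and the mm10/GRCm38 build, without roles or order; the annotation and whether counting used strand are not given in the sources used here. The deposited signal values are read counts per gene that the authors had divided by a single factor per library: from the values, each library's entries were whole multiples of the worth of 1 read for 100% of genes, within 0.001 of a whole read. TG and het tables were normalised separately, each with its own WT pair, so each genotype was tested against the WT pair of its table. Levels were set across tables only to describe the WT pairs, after centring. Each table lists only genes above a mean of about 11.2 (TG) or 17.8 (het) normalised reads, so that genes below this were not analysed here. Names turned into dates by a spreadsheet stood in 20 TG and 18 het entries, 4 of them sharing a name; these stayed in the tests, are not named, and were left out where tables were joined. The joint set holds 11754 genes. Gene positions came from GENCODE mouse release M21 on GRCm38 by symbol (99.0% of TG and 99.2% of het genes).

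Groups followed the labels: Ube3a_TG against its WT libraries, and Ube3a_het against its own, n = 2 in each. Values were taken to log2(value + 1), and a fold change is on that scale, which understates the change of low genes. The main test was limma 3.58.1 (lmFit, eBayes with trend and robust) in R 4.3.3, within each table, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The design written before the data were examined assumed raw counts and edgeR's quasi-likelihood test; because the tables hold normalised values, that test was run as an added alternative on the recovered reads (edgeR 4.0.16), where it called 0 genes in TG, 110 higher and 72 lower in het, and 44 for the difference of the effects. The difference of the effects was the contrast (TG − WT) − (het − WT) in a joint fit of 8 libraries, in which each table's scale is absorbed by its own WT pair. The test between the WT pairs was not run, since they lie in tables normalised separately. After centring, the means of the 2 pairs had a median absolute log2 difference of 0.17, with 229 genes over 2-fold. Single libraries differed by 0.161 with 260 genes within the TG table's pair, and by 0.15 with 164 within the het table's. Means of 2 libraries vary less than single libraries, so these values do not show that the pairs stand as close as replicates.

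Gene lists, 30 in number, were fixed before the data were examined from general knowledge of liver, lipid metabolism and cell type markers; 26 had at least 3 measured members in TG and 25 in het. Each was tested on the log2 values with limma's camera with a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists. The design written beforehand had planned camera on voom values, which was not run. Camera compares a list with the other genes. With the preset correlation its p-value rests on the spread across genes. With an estimated correlation it rests on the few residual degrees of freedom of the libraries. A list then has little chance of a call after adjustment, so a lost call there is weak evidence against it. Lists for the difference of the effects were tested the same way, a test added after the data were seen, as were lists for mesothelium, pericentral and periportal genes.

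Named genes followed a rule set beforehand: Ube3a; up to 6 called genes at each end of the log2 fold change with mean CPM of at least 1 and every mutant library on the same side of every WT library, without predicted gene models; up to 4 called members of each list; for steatosis and fatty acid synthesis, the 3 members of smallest p where none was called; 5 genes in each direction for the difference; Kmt2d and sex chromosome genes; genes of shared-call counts of 5 or fewer; and the 5 genes of smallest p where fewer than 10 passed. Other genes were named after their values were seen: the 3 members of smallest p of each called list, members that passed adjusted over a list alone, Scd1, Plin2, Pparg and Cd36, and most genes of the closing section. Some genes that these rules select are not reported here.

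Alternatives were DESeq2 1.42.0, limma-voom, edgeR with median-ratio factors, no robust estimates, library sizes without the 20 most abundant genes, mean CPM of at least 1, all 8 libraries in a single fit, the replicate number as a block and leaving out each library; pseudocounts of 0.5 and 5, TMM scaling and mean CPM of at least 5 were added after the data were seen. Leaving out a library leaves an arm with a single library, which is then assumed to vary like the others. The pipeline was tested on simulated data drawn from these libraries' means and depths with 200 changed genes. In TG (13774 genes) it called 24% of 2-fold and 81% of 4-fold changes, and 15 of 120 calls were false; in het (11773 genes) 74% and 96%, and 14 of 184 were false; for the difference (11754 genes) 16.1% and 80.5%, and 10 of 90 were false. DESeq2 made 46 false calls of 182 in the simulated TG comparison. Simulated genes varied independently, whereas whole lists shifted together between the real TG libraries. These rates therefore need not hold for the real data, where Ube3a itself, 4.69-fold higher in TG, did not pass limma's test. Calculations around the fits used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.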

Results

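Liver RNA was sequenced from C57BL/6 mice kept for 8 weeks on a diet with 42% fat, in 4 groups of 2 libraries. Mice homozygous for a Ube3a transgene (TG) were set against their own WT libraries, and mice with 1 knockout and 1 WT allele of Ube3a (het) against another WT pair. UBE3A is a ubiquitin ligase, and the title of the study names it as a factor acting against fat accumulation in liver through degradation of the histone methyltransferase MLL4, encoded by Kmt2d. The table for TG listed 13774 genes and that for het listed 11773. The reads recovered from the tables were 45672650 and 44193275 in the WT libraries of the TG table, 46940845 and 47928229 in TG, 15530192 and 14581137 in the WT libraries of the het table, and 17748088 and 13171145 in het. Low genes thus had fewer reads in the het table. Albumin took 5.79 to 7.94% of the values of a library and the 20 most abundant genes 20.5 to 24.7%. Libraries of the same group differed by far more than sampling noise (chi-square per degree of freedom 18.9 to 386), so none was a copy of another. The labels do not say whether the libraries of a group came from separate animals. The p-values of single genes measure only the spread between these samples, which may be technical. Those of camera with the preset correlation, and the hypergeometric and permutation p-values below, take genes as the units. A small value there is no measure of agreement between libraries. Every group had n = 2, and values are normalised read counts given as mean ± SD.

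Ube3a (ENSMUSG00000025326; chromosome 7, 59228750 to 59311536, + strand, GRCm38) was measured first as a check of the labels. It stood at 5965 ± 37.9 in TG and 1273 ± 122 in the WT libraries of that table, a 4.69-fold higher level (log2 fold change 2.23, SE 0.13, 95% interval 1.91 to 2.55). Both TG libraries (5991 and 5938) lay far above both WT libraries (1187 and 1359), although limma's adjusted p was 0.0586; DESeq2 gave adjusted p = 5.02e-34. In het the level was 290 ± 15.0 against 389 ± 28.6 in WT, a log2 fold change of −0.42 (SE 0.11, 95% interval −0.68 to −0.16). There limma's adjusted p was 0.129 and that of DESeq2 0.455. Both het libraries (301 and 280) were below both WT libraries (369 and 409), and transcripts of the knockout allele outside the deleted part may be among the reads counted. C230091D08Rik, an antisense transcript that overlaps Ube3a, had log2 fold changes of 2.25 in TG and −0.65 in het; without strand, its reads and those of Ube3a cannot be told apart. Kmt2d had log2 fold changes of 0.40 in TG (adjusted p = 0.535) and 0.14 in het (adjusted p = 0.519). These are RNA levels, which do not measure the MLL4 protein whose degradation the title names. Xist, the only gene of the sex chromosome list that was measured, was abundant in all 8 libraries (42810 to 52740 in the TG table and 13359 to 14441 in the het table), and genes of the Y chromosome were not analysed here.

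**Figure D1:**
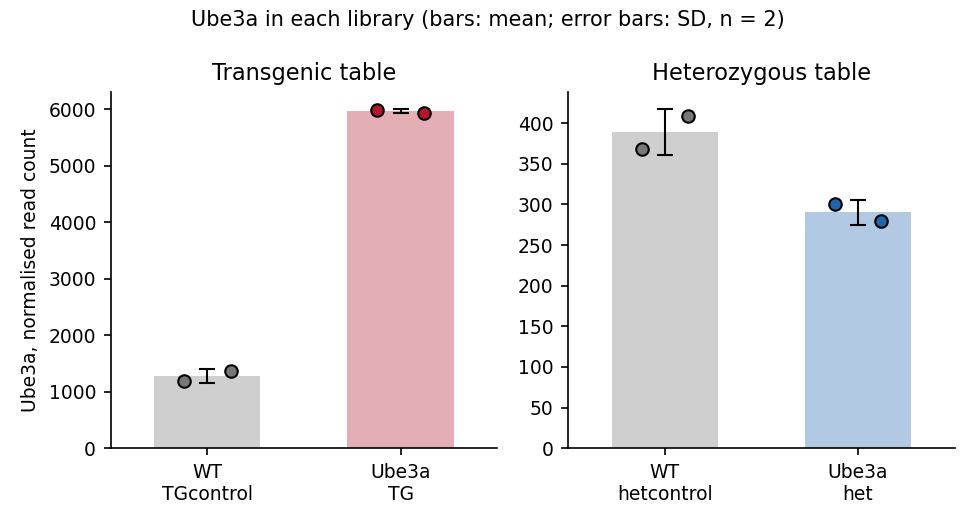
Ube3a in each library (points, normalised read count), with group mean (bars) and SD (error bars, n = 2), for the transgenic table (left) and the heterozygous table (right), which were normalised separately and have separate axes. The TG libraries stand at 5991 and 5938 against 1187 and 1359 in WT, and the het libraries at 301 and 280 against 369 and 409.

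The TG comparison addressed what additional Ube3a does to liver transcripts on the high-fat diet. Genes that store fat in lipid droplets were lower as a list: 18 of 23 measured members of the lipid droplet and steatosis list lay below the WT level, with a median log2 fold change of −0.39 (1.31-fold lower; camera adjusted p = 0.000134, and adjusted p = 0.523 with an estimated correlation). No member passed over all genes tested; adjusted over the list alone, 4 fell. These were Pparg, the adipogenic nuclear receptor, at 399 ± 39.8 against 890 ± 71.2 (log2 fold change −1.16, SE 0.15, adjusted p = 0.182 over all genes), G0s2, an inhibitor of triglyceride lipase (−1.46, SE 0.24), Mogat1, an enzyme of triglyceride synthesis (−3.84, SE 0.72), and Cidec, which enlarges lipid droplets (−2.71, SE 0.51). Cidec stood at 88.7 and 184 in TG against 595 and 1187 in WT, and Mogat1 at 11.7 and 52.1 against 359 and 383. Plin2, a lipid droplet coat protein, had a log2 fold change of −0.79 (adjusted p = 0.534). The list's median was −0.67 without TG replicate 2.

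Other lipid lists went apart, and 1 library decided them. The cholesterol synthesis list was higher in TG, with 23 of 25 members above the WT level and a median log2 fold change of 0.75 (camera adjusted p = 4.5e-05, and adjusted p = 0.785 with an estimated correlation). Hsd17b7 (0.75), Srebf2 (0.38), the transcription factor of the pathway, and Stard4 (0.82), a sterol carrier, had the smallest p there. The list of fatty acid oxidation genes and PPAR-alpha targets was lower, with 27 of 28 members below the WT level and a median of −0.49 (adjusted p = 0.000477, and adjusted p = 0.785 with an estimated correlation). Ucp2 had a log2 fold change of −0.70, while the coactivator Ppargc1a rose adjusted over the list alone (0.81, SE 0.12). Without TG replicate 1 the cholesterol median was 0.01 (adjusted p = 0.895) and the oxidation median 0.06 (adjusted p = 0.72). Without TG replicate 2 they were 1.21 and −0.97. The fatty acid and triglyceride synthesis list had a median of 0.24 with 16 of 24 members above WT (adjusted p = 0.707). It was called higher without TG replicate 2 (median 0.88, adjusted p = 4.59e-08) and lower without TG replicate 1 (median −0.46, adjusted p = 4.9e-08). Its members of smallest p were Agpat2 (−0.77, adjusted p = 0.465), Lpin1 (1.01, adjusted p = 0.541) and Dgat1 (−0.27, adjusted p = 0.589). The mean of this list differed by 1.64 log2 units between the TG libraries (14.9 in replicate 1 and 13.3 in replicate 2), and by 0.13 between their WT libraries. Scd1, the stearoyl-CoA desaturase, was at 2033370 in TG replicate 1 and 177199 in replicate 2.

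**Figure D2:**
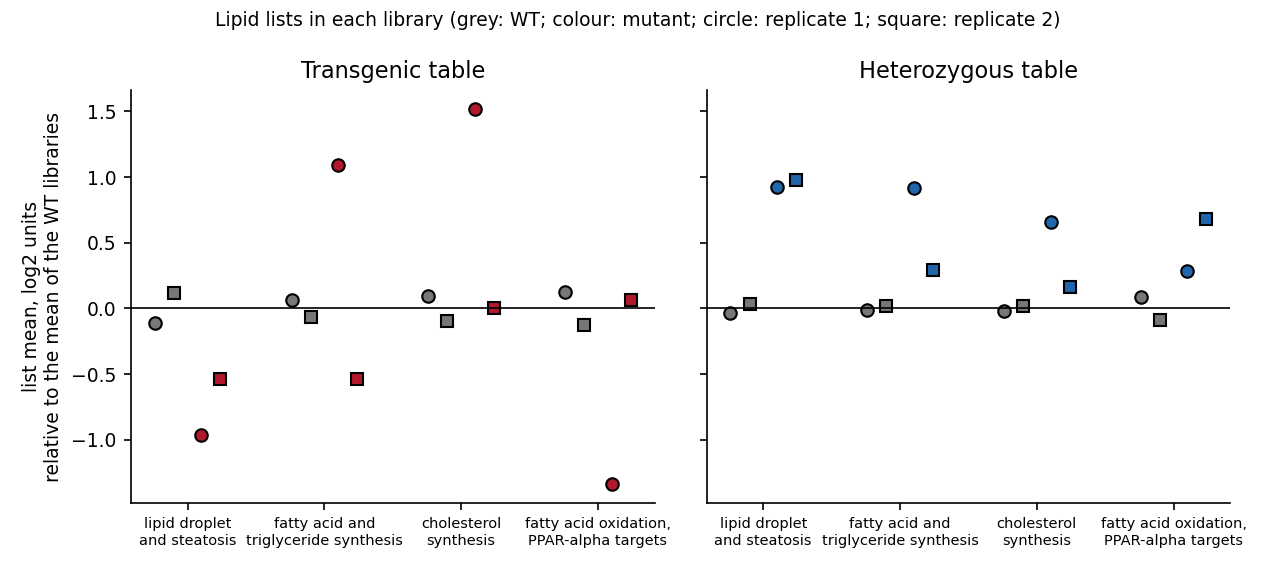
Mean of 4 lipid lists in each library, in log2 units relative to the mean of the WT libraries of the same table (grey: WT; colour: mutant; circles: replicate 1; squares: replicate 2). The TG libraries lie on the same side of WT for the steatosis list and 1.64 units apart for fatty acid and triglyceride synthesis, while both het libraries lie above WT in all 4 lists.

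Markers of other cell types and the cell cycle moved with the TG group. All 16 endothelial markers lay below the WT level (median −0.23, camera adjusted p = 4.5e-05), among them Gpr182 (−0.41) and Tie1 (−0.38). Kupffer cell and macrophage markers did so in 17 of 20 cases (median −0.34, adjusted p = 0.00074), with Cd5l at −0.71. The median of the latter was −0.17 without TG replicate 1 and −0.53 without replicate 2. The cell cycle list had 16 of 18 members below WT (median −1.01, adjusted p = 4.5e-05). Adjusted over the list alone, the replication licensing genes Mcm3 (−1.07) and Mcm2 (−1.38) fell, as did Cdkn1a (−1.88), which encodes the inhibitor p21. The circadian clock list was higher (15 of 18 members, median 0.18, adjusted p = 0.00154), with Rora at 0.51, and its median was 0.30 without WT replicate 1. For these 4 lists the estimated correlation gave adjusted p = 0.523.

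A further 4 TG lists were called with the preset correlation and lost the call when a library was left out. Xenobiotic metabolism genes were lower in 23 of 30 cases (median −0.31, adjusted p = 0.00215, and without TG replicate 1 a median of −0.03 with adjusted p = 0.0984). Gsta1 (−2.78, SE 0.28) and Gsta2 (−2.21, SE 0.24), neighbouring glutathione transferase paralogs that may share reads, fell adjusted over the list alone. Interferon response genes were lower in 19 of 23 cases (median −0.19, adjusted p = 0.0206, and 0.484 without WT replicate 2 and 0.588 without TG replicate 1, each with a median of −0.09). Its median was −0.31 without WT replicate 1 and −0.39 without TG replicate 2. The list of MLL3/MLL4 subunits and related histone enzymes was higher in 12 of 16 cases (median 0.14, adjusted p = 0.039, and 0.0664 to 0.102 without any single library; median 0.07 without WT replicate 1), with Kdm6a at 0.56 and Kmt2c at 0.36. Hepatocyte core genes were higher in 17 of 19 cases (median 0.31, adjusted p = 0.039). That call ended without WT replicate 1 (adjusted p = 0.284), WT replicate 2 (0.156) or TG replicate 2 (0.0664). Apoa1, the main protein of high-density lipoprotein, rose adjusted over that list alone (1.49, SE 0.24). With an estimated correlation the adjusted p was 0.785 for the interferon list and 0.523 for the other lists of this paragraph.

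Gene by gene, limma called 0 of 13774 genes in TG, with 1256 at an unadjusted p under 0.05 (710 higher and 546 lower). edgeR on the recovered reads called 0, limma-voom 0, and DESeq2 96 higher and 90 lower. After Ube3a and its antisense transcript, the smallest p belonged to Ces2c, a carboxylesterase with close paralogs (753 ± 15.3 against 2384 ± 70.1; log2 fold change −1.66, SE 0.11, adjusted p = 0.0794), and to Ttc39aos1, a noncoding transcript (−3.80, adjusted p = 0.102). Avpr1a, the vasopressin receptor of liver, had 2.03 (SE 0.16, adjusted p = 0.102). Of the 50 genes of smallest p with coordinates, 14 lay on chromosome 9, where chance would place 2.77, among them Gsta1 and Gsta2. Without TG replicate 2 limma called 72 genes higher and 74 lower, without TG replicate 1 it called 3 and 3, and with all 8 libraries in a single fit 14 and 11. With a library size that leaves out the 20 most abundant genes, the split at an unadjusted p under 0.05 was 438 higher and 687 lower.

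The het comparison addressed the loss of 1 Ube3a allele. Here the lipid droplet and steatosis list rose: all 22 measured members lay above the WT level, with a median log2 fold change of 0.89 (1.85-fold; camera adjusted p = 5.86e-17, and adjusted p = 0.265 with an estimated correlation). Over all genes 7 members rose, and adjusted over the list alone 17 did. Cidec (chromosome 6, 113424634 to 113435760, − strand) rose 7.98-fold, from 133 ± 8.23 to 1072 ± 176 (log2 fold change 3.0, SE 0.13, adjusted p = 6.84e-05). Plin4, another coat protein of lipid droplets, rose 6.58-fold from 223 ± 21.8 to 1489 ± 379 (2.72, SE 0.18, adjusted p = 0.0046), Mogat1 4.35-fold (2.12, SE 0.27, adjusted p = 0.0108) and Fitm1, which partitions fat into droplets, 2.04-fold (1.03, SE 0.11, adjusted p = 0.00499). The remaining called members, G0s2 (1.46), Plin2 (0.94) and Fitm2 (0.73), are named outside the rule for named genes, after their values were seen. Pparg had a log2 fold change of 1.12 (adjusted p = 0.244) and the fatty acid transporter Cd36 0.99 (adjusted p = 0.266).

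**Figure D3:**
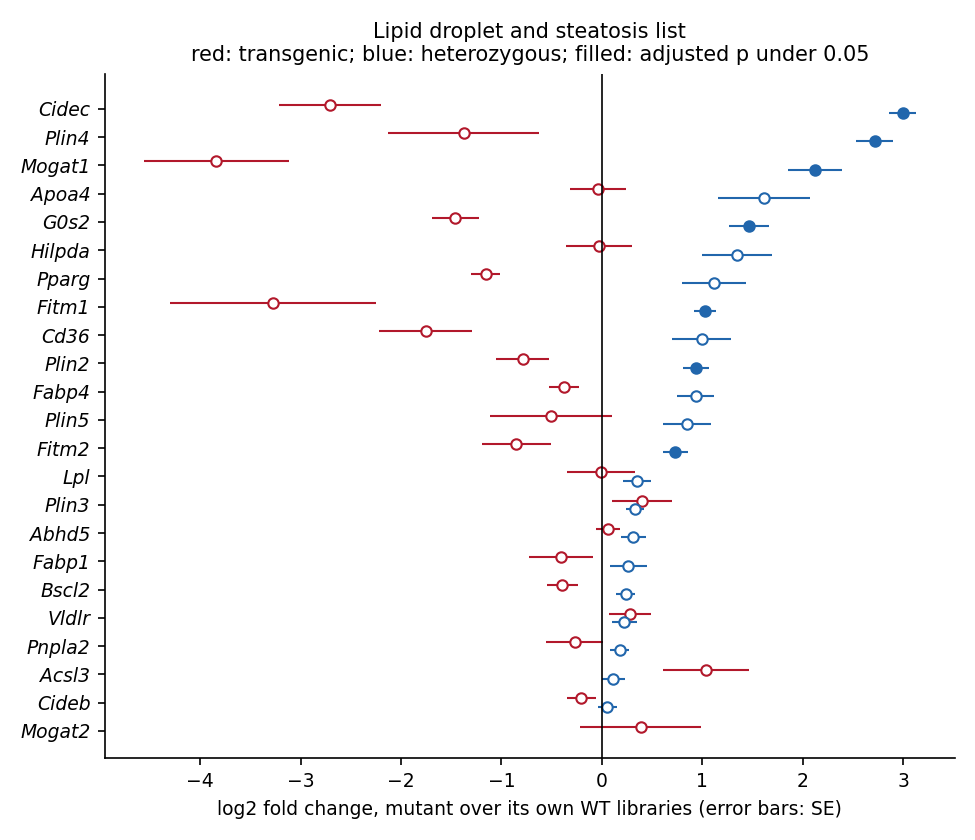
Log2 fold change of each measured gene of the lipid droplet and steatosis list (points, with SE) in TG (red) and het (blue), each against its own WT libraries; filled points have an adjusted p under 0.05 over all genes of the table. All 22 genes measured in het lie above 0 and 7 are filled, while 18 of 23 lie below 0 in TG and none is filled.

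The other lipid lists were higher in het as well. Of the fatty acid and triglyceride synthesis list, 21 of 24 members lay above WT (median 0.68, camera adjusted p = 5.77e-08, and adjusted p = 0.556 with an estimated correlation), 3 rose over all genes and 7 adjusted over the list alone. Those 3 were the fatty acid elongase Elovl5 (1.04, SE 0.16, adjusted p = 0.0295), the desaturase Fads2 (0.74, SE 0.12, adjusted p = 0.0311) and Agpat2 (0.59, SE 0.10, adjusted p = 0.0384). The median was 0.30 without het replicate 1. Fatty acid oxidation genes and PPAR-alpha targets were higher in 26 of 28 cases (median 0.36, adjusted p = 5.77e-08, and adjusted p = 0.622 with an estimated correlation). Vnn1, a PPAR-alpha target, rose (0.78, SE 0.13, adjusted p = 0.0382), and 6 members rose adjusted over the list alone, the carnitine carrier Slc25a20 (0.50) among them. Without het replicate 2 the median was 0.15. The cholesterol synthesis list was higher in 22 of 25 cases (median 0.35, adjusted p = 3.65e-07, and adjusted p = 0.686 with an estimated correlation). Hmgcs1, an early enzyme of the pathway, rose (0.80, SE 0.11, adjusted p = 0.0165), and 5 members rose adjusted over the list alone. The median was 0.16 without het replicate 1 and 0.61 without het replicate 2.

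Cell type and stress lists also moved in het. All 16 endothelial markers lay above WT (median 0.32, camera adjusted p = 4.78e-06). The lymphatic and sinusoidal receptor Lyve1 (0.92, SE 0.16, adjusted p = 0.0403) and Gpr182 (0.67, SE 0.13, adjusted p = 0.0442) rose, and 8 rose adjusted over the list alone. Kupffer cell and macrophage markers were higher in 15 of 17 cases (median 0.22, adjusted p = 0.0199), with 1 rise adjusted over the list alone, Cd163 (0.85). The median was −0.01 without het replicate 2 (adjusted p = 0.97), 0.06 without WT replicate 1 (0.933), 0.44 without het replicate 1 and 0.45 without WT replicate 2. In the cell cycle list 10 of 13 members were higher (median 0.39, adjusted p = 0.016, and 0.0532 without WT replicate 1 and 0.108, with a median of 0.17, without het replicate 1). Its called member, Cdkn1a, rose 6.73-fold (2.75, SE 0.24, adjusted p = 0.00393). Adjusted over the list alone 5 rose, the proliferation marker Mki67 (1.11) among them, and Ccnd1 fell (−0.35). NRF2 targets were higher in 11 of 12 cases (median 0.17, adjusted p = 0.00848, and 0.0643 without het replicate 1). Of these, 3 rose adjusted over the list alone (Srxn1 0.40, Gclc 0.44 and Hmox1 0.65), and the median was 0.26 without het replicate 2. Male-biased liver genes were lower in 10 of 15 cases (median −0.34, adjusted p = 0.0281, and 0.109 without WT replicate 1 and 0.0675 without het replicate 1). Nox4 (−0.80, SE 0.13, adjusted p = 0.0279) and Mup21 (−0.77, adjusted p = 0.0403), whose paralogs may share its reads, fell, and adjusted over the list alone 7 fell and 1 rose. With an estimated correlation the adjusted p was 0.796 for the Kupffer list and 0.556 for the others of this paragraph.

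**Figure D4:**
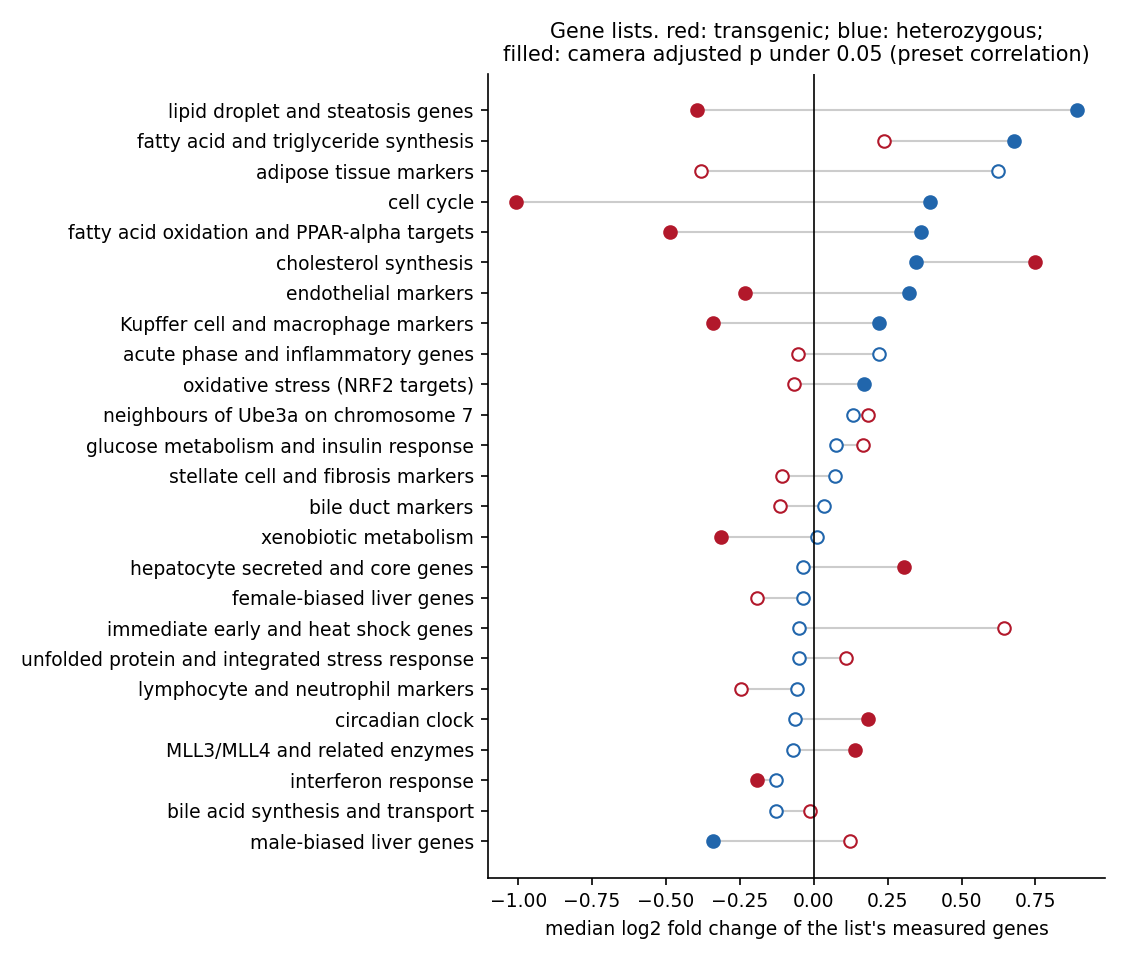
Median log2 fold change of the measured genes of each list tested in both tables (TG red, het blue; filled where camera's adjusted p with the preset correlation was under 0.05). The steatosis list stands at −0.39 in TG and 0.89 in het, the cell cycle list at −1.01 and 0.39, and cholesterol synthesis above 0 in both (0.75 and 0.35).

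In all, limma called 105 genes higher and 64 lower in het. By the rule for named genes, the largest rises besides Cidec, Plin4, Cdkn1a and Mogat1 were those of Ly6d, a surface antigen (6.64-fold, from 63.1 ± 9.31 to 427 ± 83.0; adjusted p = 0.00103), and Gpc1, a heparan sulfate proteoglycan (5.37-fold, adjusted p = 0.0393). The largest falls by that rule were those of Upk3b, a uroplakin of mesothelium and urothelium (log2 fold change −2.24, SE 0.26, adjusted p = 0.00891), Slpi, a protease inhibitor (−2.21, adjusted p = 0.0394), Sulf1, a heparan sulfate sulfatase (−1.99, adjusted p = 0.0491), and Gpm6a, a membrane glycoprotein (−1.96, adjusted p = 0.0442). These 4 had WT means of only 33.1 to 79.1. Dio3os fell as well (−1.41, adjusted p = 0.0165), a noncoding gene whose reads may be shared with transcripts of the other strand. Called members of lists that were not called were Cyp2c37 (−1.26, adjusted p = 0.00777), which has close paralogs, the aryl hydrocarbon receptor Ahr (−0.58, adjusted p = 0.0403), the bile acid and drug transporter Slco1a4 (−0.56, adjusted p = 0.0313), the steroid hydroxylase Cyp17a1 (0.76, adjusted p = 0.0155) and Jun (1.21, adjusted p = 0.0371).

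The number of het calls was 289 with DESeq2, 82 with limma-voom, 93 without robust variance estimates, and 0 with all 8 libraries in a single fit, where TG and het share the estimate of the spread. It was 65 without WT replicate 1, 61 without het replicate 1 and 105 without het replicate 2; of the 29 called genes tabulated by name, 10, 9 and 14 stayed called there and 17 without WT replicate 2. Cidec, Cdkn1a, Ly6d, Plin4, Fitm1 and Cyp2c37 were called whichever library was left out.

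The remaining lists did not pass in either table, or passed in 1. In TG the adjusted p was 0.0631 for glucose metabolism (median 0.17) and for immediate early and heat shock genes (median 0.64), 0.11 for lymphocyte and neutrophil markers (−0.24), 0.211 for exocrine pancreas (0.46, 4 members), 0.215 for the unfolded protein response (0.11), 0.228 for the neighbours of Ube3a on chromosome 7 (0.18, 9 of 16 measured), 0.413 for NRF2 targets (−0.07), 0.577 for adipose markers (−0.38), 0.742 for stellate cell markers (−0.11), 0.809 for bile acid genes (−0.01) and 0.966 for the male-biased (0.12), female-biased (−0.19), acute phase (−0.05) and bile duct lists (−0.11). Adjusted over the list alone, Srxn1 fell (−0.69), and Hsd3b5 (1.95), Adrb3 (3.60) and Cela2a (1.60) rose in TG. The mean of the immediate early and heat shock list was 8.69 and 10.7 in the TG libraries against 9.29 and 8.94 in WT, and the list was called higher without TG replicate 1 (median 1.08, adjusted p = 9.42e-13) or WT replicate 1 (0.52, adjusted p = 0.000702) and lower without TG replicate 2 (−0.35, adjusted p = 0.0329). Female-biased genes were likewise called higher without TG replicate 1 (0.35, adjusted p = 0.00647) and lower without TG replicate 2 (−0.24, adjusted p = 0.01). Without TG replicate 1 the glucose, unfolded protein and exocrine pancreas lists were called higher and the lymphocyte and stellate cell lists lower (adjusted p from 9.54e-05 to 0.0126), and without WT replicate 2 NRF2 targets were called lower (adjusted p = 0.0284). In het the adjusted p was 0.0587 for adipose markers (median 0.62), 0.0699 for bile acid genes (−0.13), 0.0768 for acute phase genes (0.22), 0.216 for the interferon list (−0.13), 0.28 for the unfolded protein response (−0.05), 0.314 for the clock (−0.06), 0.361 for glucose metabolism (0.08) and 0.467 for both the MLL3/MLL4 list (−0.07) and the neighbours of Ube3a (0.13). It was 0.72 for female-biased genes (−0.04), 0.657 for lymphocyte markers (−0.06) and 0.89 for immediate early genes (−0.05). Medians were 0.07 for stellate cell markers, 0.01 for xenobiotic metabolism, 0.03 for bile duct and −0.04 for hepatocyte core genes, with adjusted p from 0.553 to 0.625. Adjusted over the list alone, 7 glucose genes rose and 1 fell in het, 4 adipose markers rose (Pck1, Fabp4, Cfd and Lipe) and 1 fell (Adrb3), 2 xenobiotic genes rose and 3 fell, 2 female-biased genes rose and 1 fell, 2 immediate early genes rose and 1 fell, 2 bile acid genes fell, and Dbp and Cela1 fell. Leaving out a library made calls in het too: the interferon list was lower without WT replicate 1 (median −0.36, adjusted p = 4.84e-05) or het replicate 2 (−0.27, adjusted p = 0.00101), the unfolded protein list higher without WT replicate 1 (0.20, adjusted p = 0.0197) and lower without WT replicate 2 (−0.34, adjusted p = 4.78e-07), and immediate early genes likewise (0.20, adjusted p = 0.0267, and −0.30, adjusted p = 0.0468). Without WT replicate 2 the adipose and acute phase lists were called higher (adjusted p = 0.00202 and 0.00669), without WT replicate 1 xenobiotic and bile acid genes lower (adjusted p = 0.0197 and 0.0497), and without het replicate 2 bile acid genes lower (adjusted p = 0.0305). In all, 9 of the 15 lists not called in TG and 7 of the 16 in het were called without some library. The mean or the test had another sign than the median for bile acid, male-biased, bile duct and adipose lists in TG and for xenobiotic, female-biased, immediate early and lymphocyte lists in het. Skeletal muscle, erythrocyte and mitochondrially encoded lists had 1, 2 and 0 measured members in TG and 0, 2 and 0 in het, too few for a test, as was exocrine pancreas in het with 1. Of the list calls with the preset correlation, none in TG and none in het held with an estimated correlation, a test of low power here. The test fry asks whether a list's genes move, on balance, in a single direction, and compares them with no other genes. It called 0 lists in TG and 1, the steatosis list, in het.

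Because the genotypes change Ube3a in opposite directions, the difference between the TG effect and the het effect was tested over 11754 genes in a joint fit of the 8 libraries. It was called for 51 genes, 24 with the TG effect above the het effect and 27 with it below. Ube3a differed by 2.65 (SE 0.15, adjusted p = 0.00157). Cidec (−5.70, SE 0.61, adjusted p = 0.0314) and Cdkn1a (−4.63, SE 0.48, adjusted p = 0.0177) had log2 fold changes of −2.71 and −1.88 in TG and of 3.0 and 2.75 in het. Clstn3, which encodes a calsyntenin, differed by −4.38 (SE 0.28, adjusted p = 0.00157), Col5a3, a collagen chain, by −4.28 (adjusted p = 0.0442) and Lamb3, a laminin chain, by −3.54 (adjusted p = 0.0442). The effect in TG was above that in het for Adrb3, the beta-3 adrenergic receptor (4.58, adjusted p = 0.0442), Enho, the adropin gene (4.52, adjusted p = 0.0338), Avpr1a (3.82, adjusted p = 0.0394), Cdh1, the epithelial cadherin (3.40, adjusted p = 0.0496), and Aph1c (4.06, adjusted p = 0.025), a gamma-secretase subunit whose paralog Aph1b may share its reads. Aph1c and Col5a3 lie on chromosome 9. Called list members included G0s2 (−2.92), Agpat2 (−1.36), Slco1a4 (1.34), Srxn1 (−1.09) and Gpr182 (−1.07).

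**Figure D5:**
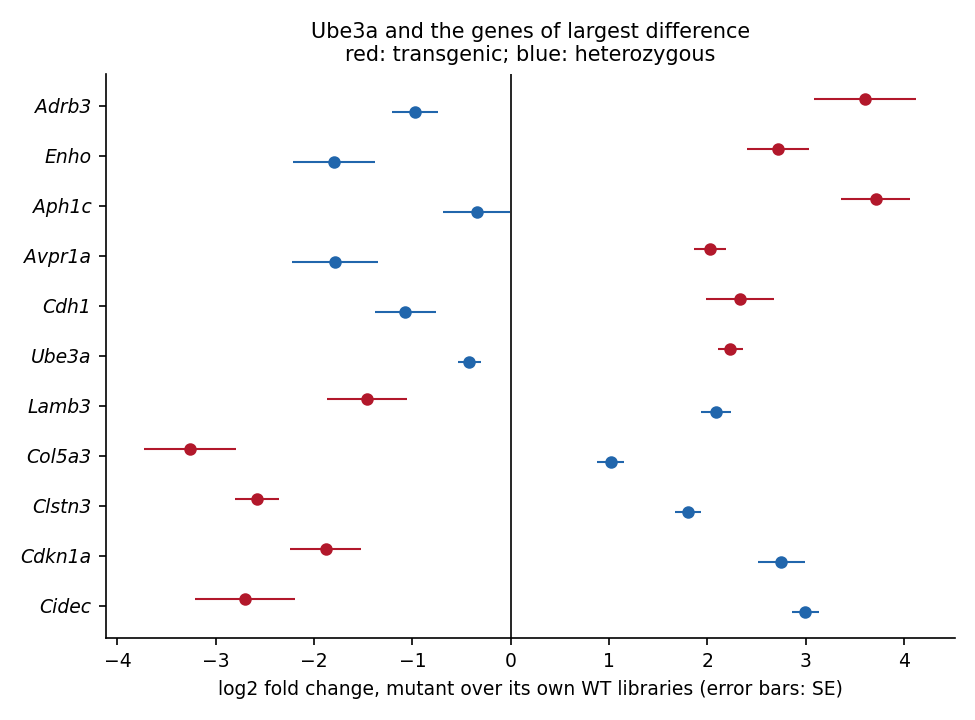
Log2 fold changes (points, with SE) in TG (red) and het (blue), each against its own WT libraries, for Ube3a and the genes named for the largest differences with adjusted p under 0.05. For each gene the effects lie on opposite sides of 0, as for Cidec at −2.71 and 3.0, though Aph1c in het lies at only −0.35. The genes besides Ube3a were chosen for the largest differences, with mutant and WT libraries fully apart in both tables. That choice favours opposite sides, so their signs are no separate evidence.

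In order of p, the lists that differed were lipid droplet and steatosis genes (median difference −1.36, camera adjusted p = 5.47e-10; 2 members called and 12 lower adjusted over the list alone), endothelial markers (−0.48, adjusted p = 1.66e-08; 1 and 8) and fatty acid oxidation genes (−0.88, adjusted p = 1.15e-05; 0 called, 3 lower and 1 higher adjusted over the list alone). The cell cycle list (−1.33, close in size to the steatosis list; adjusted p = 0.000159; 1 called, 6 lower adjusted over the list alone), Kupffer markers (−0.55, adjusted p = 0.00047; 0 and 2), the clock list (0.30, adjusted p = 0.0226) and the MLL3/MLL4 list (0.21, adjusted p = 0.0483), both with 0 members called and 0 adjusted over the list alone, also passed. With an estimated correlation the adjusted p was 0.185 for endothelial markers, 0.203 for steatosis, 0.318 for the cell cycle, clock and MLL3/MLL4 lists and 0.615 for the oxidation and Kupffer lists. The lists that fry called were 6: steatosis, endothelial, cell cycle, clock, MLL3/MLL4 and hepatocyte core genes, the last not called by camera (adjusted p = 0.106). It did not call the oxidation list (fry adjusted p = 0.465) or Kupffer markers (0.426). Without TG replicate 1 the oxidation median was −0.31 and the Kupffer median −0.36, the latter −0.34 without het replicate 2. The clock call ended without het replicate 2 (adjusted p = 0.056), its median being 0.17 without WT replicate 1 of the TG table and 0.49 without WT replicate 2, and the MLL3/MLL4 call without any library except WT replicate 2 of the het table (adjusted p from 0.0503 to 0.0892; median 0.13 without TG replicate 1). The cholesterol list, higher in both genotypes, was not called (0.36, adjusted p = 0.202), though it was without TG replicate 2 (1.02, adjusted p = 1.11e-09) and, the other way, without TG replicate 1 (−0.42, adjusted p = 0.0042); 9 of the 18 lists not called here were called without some library. The mean or the test had another sign than the median for adipose markers and for the neighbours of Ube3a. The difference was called for 371 genes with DESeq2, 31 with limma-voom, 137 without TG replicate 1 and 643 without TG replicate 2, 22 and 25 without WT replicate 1 and 2 of the TG table, 5 and 17 without those of the het table, and 6 and 7 without het replicate 1 and 2. Ube3a and Clstn3 were called in all 8 of these fits.

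No gene passed limma's test in both tables, since none did in TG. DESeq2 called 37 genes in both with opposite signs (24 lower in TG and higher in het, where chance gives 1.4, and 13 the other way, where chance gives 0.723) and 0 with the same sign. At an unadjusted p under 0.01 in both tables limma gave 40 genes with opposite signs (25 against 4.19 by chance, and 15 against 2.85) and 3 with the same sign (2 higher in both against 4.8, and 1 lower in both against 2.49): Hdhd3, Hsd17b7 and St3gal6. Among the 40 were Ube3a, changed by design, and C230091D08Rik, whose reads cannot be told apart from those of Ube3a. The chance counts take genes as independent, which they are not. At adjusted p under 0.1 in both there was 1, C230091D08Rik.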

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

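The gene test of the difference and the look at steatosis list means per library were set before their results were seen; the list test of the difference, the splits of the libraries and the comparisons with hepatocyte and adipose genes were chosen after the result was seen.

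The results here stand out because the effect of the genotype differed between TG and het in a direct test of the difference. That difference was called for 51 genes, with values (TG effect minus het effect, log2) of 2.65 for Ube3a, −5.70 for Cidec, −4.63 for Cdkn1a, −4.38 for Clstn3, −4.28 for Col5a3, −3.54 for Lamb3, 4.58 for Adrb3, 4.52 for Enho, 4.06 for Aph1c, 3.82 for Avpr1a and 3.40 for Cdh1. The calls depended on single libraries: of these genes only Ube3a and Clstn3 stayed called whichever was left out, of the 17 called genes tabulated by name 2 or 3 stayed without any library of the het table, and without WT replicate 1 of that table the total was 5. Among lists the median difference was −1.36 for lipid droplet and steatosis genes, −0.88 for fatty acid oxidation, 0.30 for the clock, 0.21 for the MLL3/MLL4 list, −1.33 for the cell cycle, −0.55 for Kupffer markers and −0.48 for endothelial markers. None of these list calls held with camera's estimated correlation (adjusted p from 0.185 to 0.615), a test with few residual degrees of freedom. The MLL3/MLL4 call ended without any library except WT replicate 2 of the het table, and the clock call ended without het replicate 2.

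The pattern a biologist would follow is the mirror image of steatosis genes, lower with additional Ube3a and higher with an allele lost. Adipose tissue as the source of the rise of Cidec in het is argued against: Cfd and Fabp4, abundant in fat cells, together gained 0.153 of the reads that Cidec gained (30.6 and 113 against 939). Some fat in the het samples is not excluded. Cfd rose from 7.64 to 38.2, and the median of the adipose list was 0.62 (camera adjusted p = 0.0587). Adjusted over the list alone, 4 of the 6 measured markers rose. Among these were Pck1, also a gene of gluconeogenesis, and Fabp4, also in the steatosis list, which speak less for fat tissue. Variation between animals of a genotype stays open, since across genes the effects correlated with Pearson r = −0.316 (Spearman −0.257; genes are not independent replicates) and another split, with TG intact and het divided by replicate number, reached an absolute r of 0.269. In the steatosis list the nearest TG and WT libraries were 0.423 apart while the TG libraries differed by 0.427. In het the gap was 0.89, well above the largest difference within a group of that table, 0.067. With n = 2 in each group, genotype and animal cannot be told apart in either table. Another mix of cell types stays open in both tables: hepatocyte core genes moved by −0.779 of the list's median in TG and −0.0408 in het, but their high level in liver would hide a small change of share, and endothelial and Kupffer markers moved the same way as the steatosis list (medians −0.23 and −0.34 in TG, 0.32 and 0.22 in het). The dose of Ube3a, which the design names, remains a hypothesis.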

How the results depend on the processing

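The added pseudocounts, TMM scaling, edgeR on recovered reads, the CPM minimum of 5 and the list test of the difference were chosen after the data were seen. Of 128 effects of called lists and of genes named by the rule or as the members of smallest p of called lists, 39 kept their direction and side of the threshold under all alternatives run and 126 their direction; lists not called and most genes named after their values were seen are not among the 128. Of 24 effects of such genes 1 changed direction, Scd1 in TG (−2.43 to 1.09; −0.67 in the main test and 0.20 with DESeq2). DESeq2 called 96 higher and 90 lower in TG, 189 and 100 in het, 371 for the difference and 37 with opposite signs in both tables. A single fit of all 8 libraries called 14 and 11 in TG and 0 and 0 in het, where the wider spread of the TG libraries enters the estimate. limma-voom called 51 and 31 in het and 31 for the difference, and limma without robust estimates 58 and 35 in het. Adjusted p under 0.1 in both tables gave 1 gene with opposite signs, and unadjusted p under 0.01 gave 40, with 3 of the same sign. Ube3a in TG stayed at 2.23 and passed with DESeq2 and in the single fit of 8 libraries. An estimated correlation, which leaves few degrees of freedom, called 0 lists in TG, 0 in het and 0 for the difference. The steatosis medians of −0.39 and 0.89 were no longer called there. In TG and het fry, which asks another question, called 0 and 1. Leaving out each library gave 0 to 72 higher and 0 to 74 lower genes in TG, 38 to 130 and 17 to 43 in het, 5 to 643 for the difference, 0 to 14 shared with opposite signs and 0 to 3 with the same sign, 2.13 to 2.33 for Ube3a in TG, and 6 to 14 lists for the difference. Among called lists it turned the direction of the median of fatty acid oxidation in TG (−0.97 to 0.06) and of Kupffer markers in het (−0.01 to 0.45). Over all lists tested, called or not, it turned 13 of 26 medians in TG, 10 of 25 in het and 8 of 25 for the difference, among them in TG fatty acid synthesis (−0.46 to 0.88), female-biased (−0.19 in the main test and 0.35 without TG replicate 1) and immediate early genes (−0.35 to 1.08), in het the unfolded protein list (−0.34 to 0.20), and cholesterol synthesis for the difference (−0.42 to 1.02). Apart from the changes of sample or estimator named, the cause was not tested. With the replicate number as a block (replicate block), 0 and 0 genes were called in TG, 87 and 51 in het (101 of the 169 main calls among them), 46 for the difference (22 of the 51 main calls among them, and 7 of the 17 called genes tabulated by name), and 12, 12 and 6 lists; same-numbered libraries deviated with correlations of 0.107 in TG and −0.0426 in het and share only a number. No filter at all equals the main setting, and a mean CPM of 1 removes no gene in het, so these say nothing on stability there. List tests were not run under edgeR or DESeq2. Those planned on voom values were not run either, so the stability of lists under these methods is unknown. The het libraries hold 13171145 to 17748088 reads against 44193275 to 47928229 in the TG table, so low genes have fewer reads in het.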

Other observations

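The mesothelium, pericentral and periportal lists were drawn up after called genes had been seen, with those genes left out and before their other members were looked at. The comparison of depth and of lipid synthesis between the TG libraries was set before its result was seen. The tests of a wrong genotype label and of chromosome 9 and the look at immediate early genes were chosen after it.

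Some genes of hepatocytes around the central vein were lower in het. Notum, a secreted inhibitor and target of Wnt signalling, fell from 981 ± 107 to 431 ± 42.8 (n = 2, log2 fold change −1.18, SE 0.12, adjusted p = 0.00386), and Rnf43, another Wnt target, by 0.67 (adjusted p = 0.0279); Notum stayed called without any single library. The call of Rnf43 was lost without WT replicate 1 (adjusted p = 0.101), WT replicate 2 (0.0675) or het replicate 1 (0.135). The hypothesis of a wider shift of pericentral genes was tested on 20 others, of which 15 lay below WT (median −0.22; camera p = 0.000205, and p = 0.302 with an estimated correlation), with Glul at −0.13 and Axin2 at −0.10. Lgr5 (−1.06, adjusted p = 0.317) was 25.0 and 61.0 in the het libraries against 80.0 and 85.1 in WT, and Cyp7a1 (−1.48, adjusted p = 0.572) was 2283 and 7735 in the WT libraries. In TG 13 of the 20 lay above WT (median 0.20), where limma's camera gave 0.128 as its p-value (adjusted p = 0.383 over the 3 added lists). The 13 periportal genes had medians of 0.14 in het (adjusted p = 0.25) and −0.06 in TG (adjusted p = 0.477). None of the 20 was called and 5 lay above WT in het, so the wider shift was small and uneven, and whether the lower Notum belongs to the genotype or to these animals cannot be told with n = 2.

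Among the largest falls in het was Upk3b, a gene of the mesothelium that covers the liver. A candidate explanation is less surface tissue in the het samples. It was tested on other mesothelium markers, and all 4 that were measured lay below WT: Igfbp6 (−2.09), Msln (−1.36), Gas1 (−0.44) and Efemp1 (−0.59), with camera p = 2.96e-05 and p = 0.0665 with an estimated correlation. Stellate cells and fibroblasts of liver also express Igfbp6, Gas1 and Efemp1, so the marker that speaks for mesothelium is Msln (62.2 ± 12.1 in WT and 23.7 ± 5.50 in het, n = 2). In TG 9 of 14 markers lay above WT (median 0.23, adjusted p = 0.525). The falls of Upk3b, Slpi, Sulf1 and Gpm6a in het may therefore come from how the piece of liver was taken.

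The TG libraries differed from each other more than those of any other group. Depth does not account for it, since their recovered reads had a ratio of 1.02. Nor does a wrong genotype label, since the lower Ube3a value in TG was 4.37 times the higher one in WT. Ube3a cannot show whether a label other than the genotype was wrong. Their mean of the fatty acid synthesis list differed by 1.64 log2 units, against at most 0.623 in any other pair of a group, with Scd1 higher in replicate 1 and Pck1, a gene of gluconeogenesis, higher in replicate 2 (45345 and 229468). The immediate early and heat shock list differed more, by 1.99 log2 units, against at most 0.417 in any other pair, and was higher in replicate 2. A different feeding state, or handling or stress around collection, may underlie this; the labels cannot test these explanations.

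Chromosome 9 held 14 of the 50 genes of smallest p in TG with coordinates (2.77 by chance, exact hypergeometric p = 3.37e-07, chromosome chosen after it was seen) and 21 of 100 (5.55 by chance), spread from 21.2 to 106 Mb, 7 higher and 7 lower. They include S1pr5 (1.74), Mcam (−1.74), Aph1b (2.02), Aph1c (3.71) and the Gsta1 and Gsta2 paralogs, so chance placement is argued against. Variants carried along with the transgene could give such a cluster if it had inserted there, a position the sources used here do not give. That would leave the het effects of these genes unrelated to the TG effects. Counting the glutathione transferase family as 1 gene, the mean het effect in the mirrored direction was 0.331 (95% bootstrap interval 0.109 to 0.571) on chromosome 9. It was 0.431 for the other top genes (one-sided permutation p = 0.276). Linked variants alone would place the mean on chromosome 9 near 0, and its interval lies above 0. That interval takes genes as the units, however, and is no measure of agreement between libraries. Linked variants behind some of these genes and the dose of Ube3a therefore cannot be told apart.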
